A study of Homo sapiens with 12 samples.

How the data were processed

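The study mapped where the human translation initiation factor eIF3 touches RNA in 293T cells, a transformed human embryonic kidney line. Per the labels' protocols, cells received 100 µM 4-thiouridine for 14 h, a uridine analog that crosslinks to bound protein under ultraviolet light and is then read as C in place of T. Cells were crosslinked at 0.15 J per square cm, eIF3 was immunoprecipitated with an antibody against its subunit eIF3b, RNA was trimmed with RNase T1, and protein-RNA complexes were cut from a denaturing gel. Per the labels, libraries were made for eIF3a, eIF3b, eIF3d and eIF3g in 3 replicates each, 12 in all, and no control library is among them. Replicate 1 carried a random barcode at the 5′ end. Nothing in the labels says whether the replicates came from separate cultures.

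The values come from 1 table of clusters, in which each line is a cluster of 1 subunit with its gene, hg19 position, strand, annotation, read count and number of T-to-C conversions. The read counts are whole numbers that the authors deposited without normalization, per the file headers. The table has no column for the replicate, so each value is the authors' pooled value and carries no SD or n. The build hg19 and the tools cutadapt, Bowtie and bedtools are named in the submitters' processing notes without versions. The cluster caller, its thresholds, the way the 3 replicates were combined and the use of the barcode are not given in the sources used here. No cluster had fewer than 8 reads. Whether positions count from 0 or 1 is not given in the sources used here, and they are printed as the authors' table gives them.

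The table held 1477 clusters under 480 gene names. A pair of names that differed only in case shared an Ensembl ID and was joined, which left 479 genes. Symbols and older symbols of 455 genes matched a RefSeq table of the GRCh38 assembly, 42 of them through an older symbol, and 444 of these were protein-coding. That table was used for names, for the number of 20056 protein-coding genes and for small RNA genes lying inside a host gene, and none of its coordinates is printed. One gene name had been turned into a date and was left unmatched. The authors' classes of long noncoding, mitochondrial, ribosomal, micro-, piwi and miscellaneous RNA were put together as noncoding RNA. Clusters of different subunits on the same strand that overlapped by at least 1 nt were joined into 558 loci.

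Region shares were given with Wilson intervals at 95% and compared for 6 pairs of subunits and 3 regions (5′ UTR, CDS, 3′ UTR) with a two-sided Fisher's exact test. Shared genes were tested with Fisher's exact test against the protein-coding genes of the reference table, which does not control for expression. Reads at shared loci were compared on the scale of log2(reads + 1) with a two-sided permutation test that flips the sign of each locus's difference, with 100000 resamples. The number of conversions was divided by the number of reads. Events without conversion are not a column of the table, so a conversion share with its interval, as first intended, was not computed, and medians carry bootstrap intervals from 10000 resamples. For 19 gene lists, the members with a cluster in a subunit were compared with the other genes of the table by a two-sided Fisher's exact test, and as a description with all protein-coding genes. Adjusted p-values follow Benjamini and Hochberg within each family, with a threshold of 0.05. Clusters and genes are not replicates and all 4 subunits came through the same antibody, so these tests describe the deposited lists and do not measure the spread between libraries. Intervals cover counting error only.

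Depth per library is unknown, because only reads inside clusters are tabulated. A test on read counts per library with edgeR, the analyses that leave out a replicate, and base composition of the clusters, which needs the hg19 sequence, were set out before the data were examined and are not analysed here.

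The genes named were fixed by rule before the data were examined. They are the 10 genes with the strongest cluster by reads in each subunit, the 15 genes with the highest summed reads among those listed for all 4 subunits, JUN and BTG1, and up to 4 members of each gene list with the highest summed reads. JUN and BTG1 were known beforehand as studied eIF3 targets, and both are also members of gene lists. Genes named outside this rule are said to be so. A few genes that the rule takes are not reported here. Alternatives were a cluster list limited to reads at or above the subunit's median, genes in place of clusters, other definitions of region and overlap, a pseudocount of 0.1, ranks, and other backgrounds for the lists. Added after seeing the data were the removal of loci with 1.9 or more conversions per read, a joint class of start codon and 5′ UTR, scaling by the reads in clusters, regions without EIF3A, strength only at loci where the clusters of both subunits overlap themselves and are not joined through a cluster of another, and 3 other summaries of conversion.

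The tests were first tested on simulated data. With no difference between subunits, 5.5% of 200 simulated tables of 1477 clusters gave any region call, and a shift of 15 percentage points in 1 subunit was called in 90.2% of the affected pairs. The simulated clusters were drawn independently for each subunit, while the real lists share many sites, so these 2 rates may not hold for them. For reads of eIF3a and eIF3b at 229 loci, 6% of 200 simulations without a shift were called and 97.5% of those with a log2 shift of 0.3. Among 479 genes, 1.5% of 200 simulations without a difference gave a call for any list. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.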

Results

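Crosslinked RNA was sequenced for eIF3a, eIF3b, eIF3d and eIF3g, subunits of the factor that brings the small ribosomal subunit to mRNA, from 293T cells labelled with 4-thiouridine. The 12 libraries form 4 groups of 3 replicates, and the table gives 1 pooled value per cluster and subunit. The clusters of eIF3a held 15132 reads, those of eIF3b 19187, those of eIF3d 24150 and those of eIF3g 62405, and median reads per cluster were 22, 19, 23 and 20. With no replicate column, no value below has a spread between libraries.

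The question of the first comparison was where on RNA each subunit was found and how strongly. BTG1, which encodes an anti-proliferative protein, was among the 10 leading genes of every subunit. In eIF3a the 2 strongest clusters were in the BTG1 5′ UTR, with 684 reads, and in LIMCH1, an actin-associated protein, with 677 reads in an intron. UBE2D2, a ubiquitin-conjugating enzyme, followed with 554 reads in its 5′ UTR (chromosome 5, 138941230 to 138941280, plus strand, the span over all subunits). In eIF3b and eIF3d the strongest clusters lay in the coding sequence of EIF3A, the mRNA of an eIF3 subunit, with up to 1963 and 3315 reads. In eIF3g the strongest clusters lay in noncoding or intronic parts of snoRNA host genes and in a lincRNA: SNHG1 with 14879 reads (chromosome 11, 62621139 to 62621166, minus strand), the lincRNA RP11-329L6.1 with 7707, GAS5 with 6165 and an intron of GNL3, a nucleolar GTP-binding protein, with 4929. The name RP11-329L6.1 matched no gene of the reference table, so whether it hosts a snoRNA was not determined.

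The eIF3a list had 375 clusters in 328 genes, eIF3b 298 in 264, eIF3d 403 in 356 and eIF3g 401 in 351. The 5 strongest clusters held 17.5% of the reads in eIF3a, 34.0% in eIF3b, 38.1% in eIF3d and 59.0% in eIF3g. DDX39B, an RNA helicase of mRNA export, was among the 10 leading genes of eIF3a, eIF3b and eIF3d, with 361, 665 and 451 reads in its 5′ UTR (chromosome 6, 31508375 to 31508402, minus strand). MLF2 had 220 reads in eIF3a and 345 in eIF3b, GLO1, a glyoxalase, had 344 reads in eIF3b and 76 in eIF3a, and PTGES3, a co-chaperone, had 192 reads in eIF3a and 239 in eIF3b. MARCKS, MORF4L2, AMOT and PPP3R1 were also listed for all 4 subunits, with 595, 682, 683 and 684 reads summed over their clusters. EIF3H had a single cluster, in eIF3a, with 370 reads in its 3′ UTR. Reads per library are unknown, so totals are not comparable between subunits as amounts of bound RNA.

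The second comparison asked in which part of the mRNA each subunit was crosslinked. Clusters in 5′ UTRs made up 67.7% of the list in eIF3a (95% Wilson interval 62.8 to 72.3, 254 of 375 clusters), 65.8% in eIF3b (60.2 to 70.9), 68.7% in eIF3d (64.0 to 73.1) and 68.3% in eIF3g (63.6 to 72.7). Coding exons made up 11.2%, 11.1%, 9.43% and 7.98%, while 3′ UTRs held 2.13%, 2.35%, 1.49% and 1.75%. Clusters called at the start codon were 4.0%, 3.02%, 4.22% and 3.74%, and those in introns 8.0%, 8.72%, 7.94% and 9.23%. Over all 4 lists, 1001 of 1477 clusters were in 5′ UTRs, in 331 genes that include JUN, BTG1, CCNG1, U2AF2 and RPS15A.

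**Figure D1:**
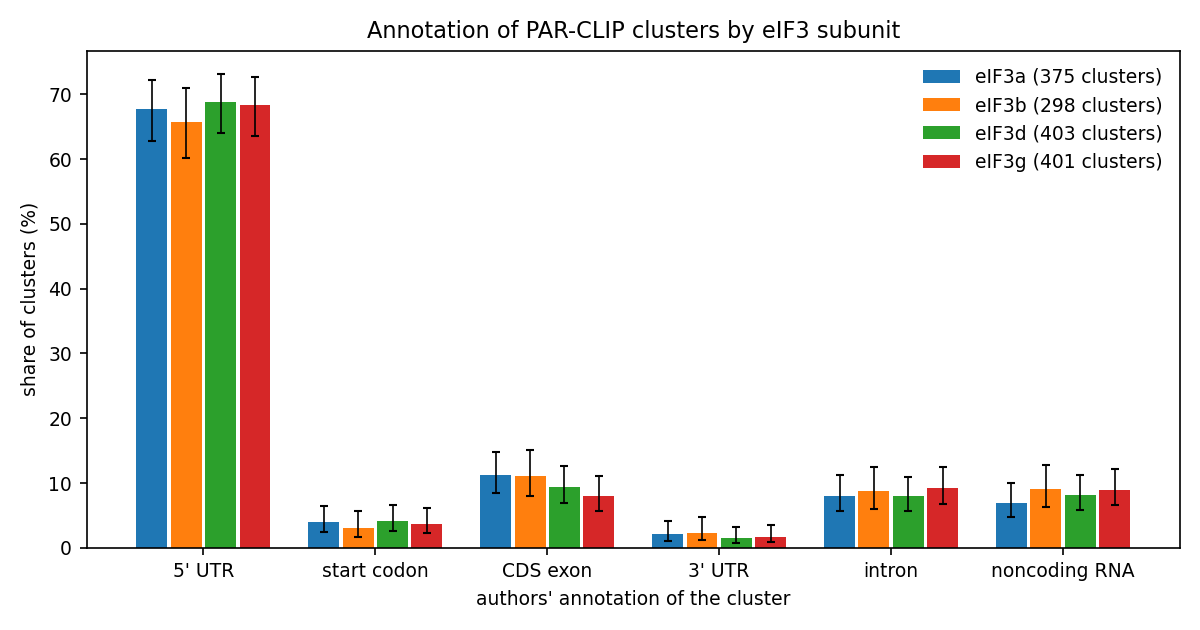
Share of clusters (%, vertical axis) in each annotation class, with 1 bar per eIF3 subunit and 95% Wilson intervals as error bars. The 5′ UTR bars of the 4 subunits lie between 65.8% and 68.7%, and every other class is at or below 11.2%.

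None of the 18 two-sided Fisher's exact tests of regions between subunits passed, with 0 under an unadjusted 0.05 and a smallest unadjusted p of 0.143 for the coding share of eIF3a over eIF3g. Among 5′ UTR shares the widest difference, eIF3b minus eIF3d, was -2.96 percentage points (95% interval -10.0 to 4.0). These tests and intervals treat the 2 lists of a pair as independent. Yet 228 of the 298 eIF3b clusters overlapped a cluster of eIF3d, so they do not settle how small a shift could have been detected. When sites shared by the pair were left out, 1 of 18 tests passed: coding exons held 25% of the 64 clusters found in eIF3b and not in eIF3g, and 8.93% of the 168 found in eIF3g and not in eIF3b (Fisher's exact test, adjusted p = 0.0413). Of the 16 eIF3b clusters behind that share 4 were in EIF3A, and without this gene, left out after seeing the data, the share was 12 of 60 and 0 of 18 tests passed (adjusted p = 0.309 by Fisher's exact test). By reads, coding exons held 31.6% in eIF3b and 29.1% in eIF3d, against 8.35% in eIF3a and 1.51% in eIF3g, but EIF3A alone gave 5464 of the 6054 coding reads in eIF3b and 6132 of 7039 in eIF3d. Without EIF3A the coding share of reads, computed after seeing the data, was 5.98% in eIF3a, 4.30% in eIF3b, 5.03% in eIF3d and 1.43% in eIF3g. Noncoding RNA held 62.8% of the reads in eIF3g and 8.21%, 8.57% and 11.5% in eIF3a, eIF3b and eIF3d.

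JUN and BTG1, a proto-oncogene transcription factor and an anti-proliferative gene, each had 1 cluster in their 5′ UTR, listed for every subunit. On chromosome 1, minus strand, the JUN cluster ran from 59249572 to 59249605 in eIF3a, eIF3b and eIF3g and ended at 59249600 in eIF3d. It held 138 reads in eIF3a, 100 in eIF3b, 286 in eIF3d and 1735 in eIF3g. The BTG1 cluster on chromosome 12, minus strand, started at 92539487 in eIF3a, eIF3b and eIF3g and reached 92539600 in eIF3a, with 684, 372, 2256 and 3109 reads in eIF3a, eIF3b, eIF3d and eIF3g. Among the 284 loci shared by eIF3a and eIF3g, the ratio of eIF3g over eIF3a reads of JUN, 12.6, lay at percentile 98.6 and that of BTG1, 4.55, at percentile 95.4. Conversions per read in eIF3a, eIF3b, eIF3d and eIF3g were 0.565, 0.80, 0.0699 and 0.0818 in JUN and 0.108, 0.220, 0.0080 and 0.0946 in BTG1.

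**Figure D2:**
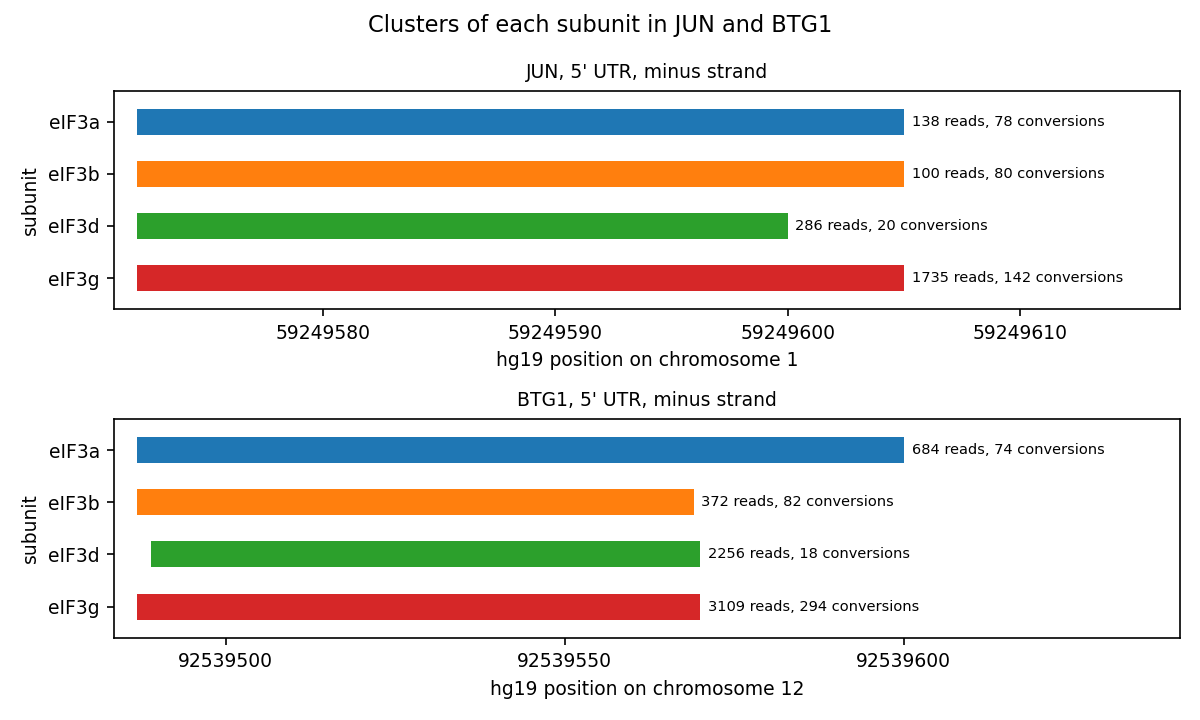
Extent of the cluster of each subunit in the 5′ UTRs of JUN (upper panel) and BTG1 (lower panel), with hg19 position on the horizontal axis and reads and T-to-C conversions printed beside each bar. The JUN bars of all 4 subunits start at 59249572, and eIF3g has the most reads in both genes, 1735 and 3109.

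The third comparison asked how far the subunits shared their targets. Of 479 genes, 161 (33.6%) were listed for all 4 subunits, 113 for 3, 111 for 2 and 94 for 1. The genes of all 4 subunits with the most summed reads were EIF3A with 12026, BTG1 with 6421, the mitochondrial ribosomal RNA MT-RNR2 with 4726, JUN with 2259, DDX39B with 1783 and UBE2D2 with 1618. TPT1, a growth-associated translationally controlled protein, had 172, 57, 112 and 368 reads in eIF3a, eIF3b, eIF3d and eIF3g. Genes listed for a single subunit had fewer reads, with a median strongest cluster of 13 reads in eIF3g and 16 in eIF3d, against 29 and 37 for genes of all 4 subunits.

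**Figure D3:**
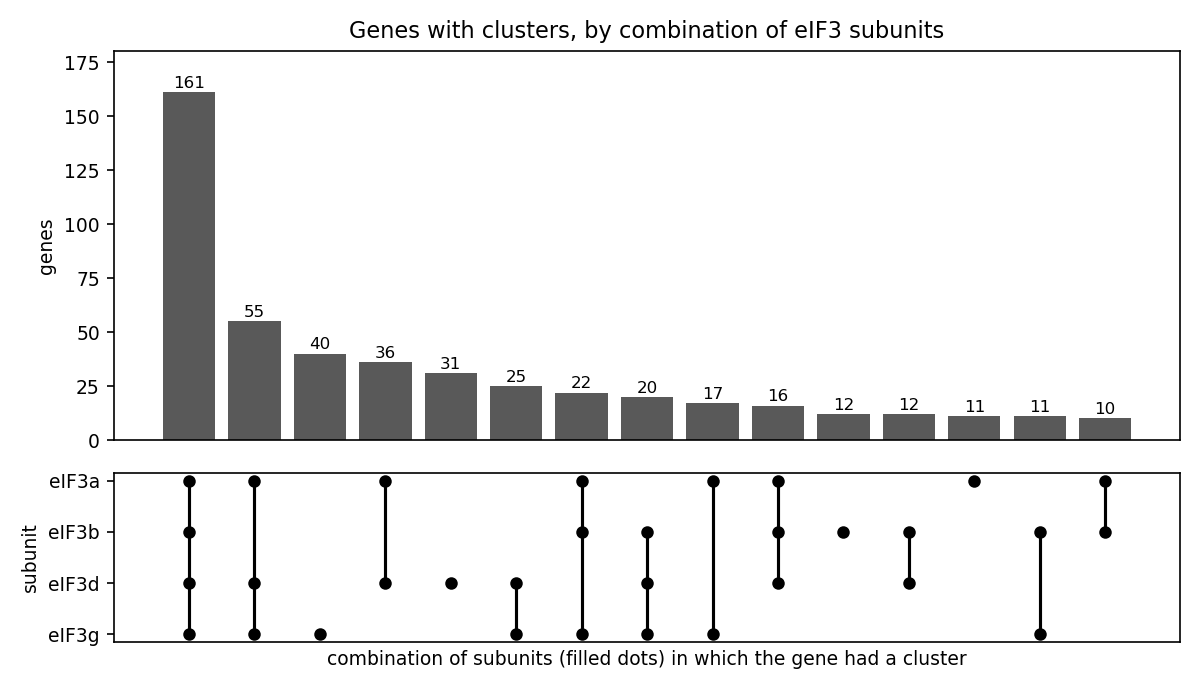
Number of genes (vertical axis) for each combination of eIF3 subunits in which they had a cluster, marked by filled dots below. The bar for all 4 subunits holds 161 genes, and the next, eIF3a with eIF3d and eIF3g, holds 55.

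Shared genes ran from 209, both for eIF3a with eIF3b and for eIF3b with eIF3d, to 268 for eIF3a with eIF3d. They were between 74.4% and 81.7% of the shorter list of a pair. Against 20056 protein-coding genes, 251 were shared by eIF3a and eIF3d where independent lists would share 5.05 (Fisher's exact test, odds ratio 1122), and every one of the 6 pairs had an adjusted p at or below 1.86e-318. The subunits came through 1 antibody and expressed genes were not separated from silent ones, so this overlap is not independent evidence. By position, 173 of 558 loci were listed for all 4 subunits.

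Reads at shared loci were compared next, to ask whether one list held more reads where both subunits were found. The counts are not scaled and depth per library is unknown. A median shift can therefore come from depth alone, and the tests do not measure crosslinking strength. At 229 loci shared by eIF3a and eIF3b the median log2 difference of eIF3b from eIF3a was -0.26, lower at 137 and higher at 85 loci (permutation test, adjusted p = 0.00246). For eIF3d it was 0.14 from eIF3a over 299 loci (adjusted p = 0.0059 by permutation) and 0.35 from eIF3b over 230 loci (adjusted p = 0.00018 by permutation). For eIF3g it was 0.00 from eIF3a, 0.21 from eIF3b and -0.03 from eIF3d, with adjusted permutation p of 1, 0.0761 and 0.66. Single genes spread around these medians: from eIF3a to eIF3b reads went from 76 to 344 in GLO1 (percentile 97.4 of the log2 differences of that pair), from 220 to 345 in MLF2 (percentile 78.6) and from 172 to 57 in TPT1 (percentile 9.61). Scaled by the reads in clusters, the difference of eIF3b from eIF3a kept its direction at -0.61 (adjusted p = 1.2e-05 by permutation), that of eIF3d from eIF3a turned to -0.52 and that of eIF3d from eIF3b was 0.034 (adjusted p = 0.517 by permutation). With that scaling, chosen after seeing the data, eIF3g was lower than eIF3a by 2.04, than eIF3b by 1.48 and than eIF3d by 1.40 (adjusted p = 1.2e-05 by permutation each). Thus eIF3b reads lay below eIF3a reads with and without the scaling, which does not separate depth from crosslinking. The places of eIF3d and eIF3g in the order depended on the scaling. The scaled sizes also depend on EIF3A, which gave 5464 of 19187 reads in eIF3b and 6132 of 24150 in eIF3d. In eIF3a it gave 382 of 15132. The eIF3g differences depend on noncoding RNA, which gave 39165 of 62405 reads in eIF3g and 1243 of 15132 in eIF3a. They can therefore come from the denominator and do not show weaker crosslinking of eIF3g at shared loci. A scaling without EIF3A or without noncoding RNA was not run. Limited to clusters at or above the median reads, without scaling, the difference of eIF3d from eIF3a was 0.086 and no longer passed (adjusted p = 0.135 by permutation).

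T-to-C conversions mark crosslinked uridines. Conversions per read in eIF3a, eIF3b and eIF3g had medians of 1.02 (95% bootstrap interval 1.0 to 1.04), 1.05 (1.02 to 1.08) and 1.02 (1.0 to 1.05), and in eIF3d of 0.182 (0.167 to 0.2). As summed conversions over summed reads, a summary chosen after seeing the data in which strong clusters weigh most, the values were 0.917 in eIF3a, 0.847 in eIF3b, 0.0865 in eIF3d and 0.281 in eIF3g. UBE2D2 had 622 conversions in 554 reads in eIF3a and 11 in 589 reads in eIF3d, DDX39B had 803 in 665 reads in eIF3b and 10 in 451 reads in eIF3d, and MLF2 had 344 in 345 reads in eIF3b and 2 in 74 reads in eIF3d. At the 173 loci of all 4 subunits, eIF3d was lower than eIF3a at 173, lower than eIF3b at 170 and lower than eIF3g at 170 (permutation p = 1e-05 each, the smallest they can give, adjusted p = 2e-05, in a comparison chosen after seeing the data). The other 3 pairs did not pass, with adjusted p from 0.401 to 0.819 by permutation. The clusters of EIF3A, EIF3B, EIF3H, EIF3K and EIF3M carried between 0.04 and 0.23 conversions per read in eIF3a, eIF3b and eIF3g, and EIF3B and EIF3K are named here after their values were seen. Across clusters, which are not replicates, the slope of log2 conversions on log2 reads was 0.287 in eIF3d, against 0.877 in eIF3a, 0.911 in eIF3b and 0.546 in eIF3g, so what the eIF3d conversion entries count is uncertain.

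**Figure D4:**
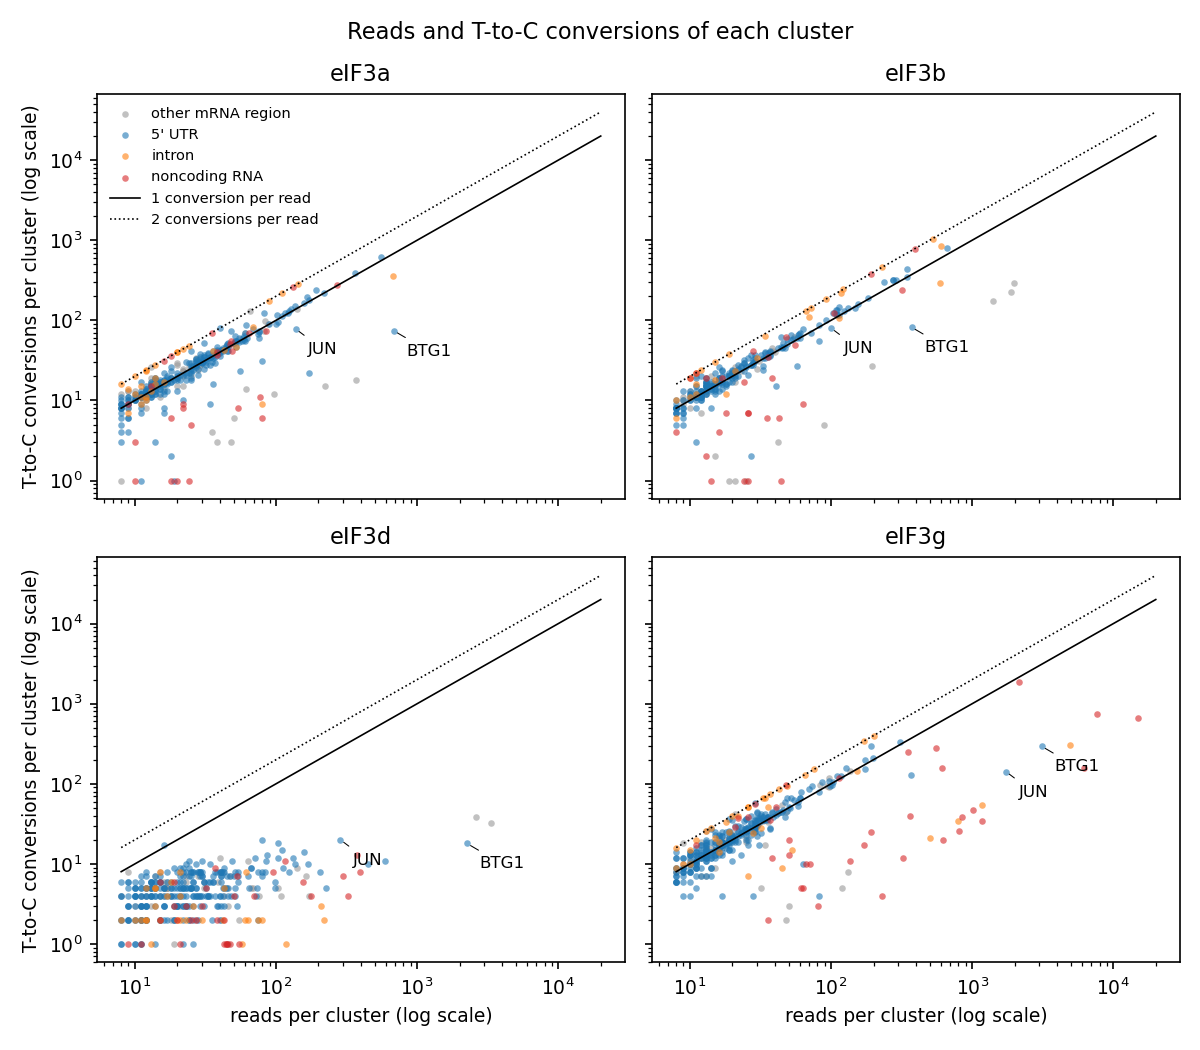
T-to-C conversions against reads for each cluster, both on log axes, with 1 panel per subunit, points coloured by annotation and lines at 1 and 2 conversions per read. Medians are 1.02, 1.05 and 1.02 in eIF3a, eIF3b and eIF3g and 0.182 in eIF3d, and the EIF3A clusters in eIF3b and most clusters of snoRNA host genes in eIF3g lie below the line of 1.

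Gene lists fixed beforehand showed which kinds of gene were in the table, where a member counted with a cluster of any annotation, introns included. Of translation factors and regulators, 13 genes had a cluster and 8 were listed for all 4 subunits, led by EIF3A, EIF3M with 743 summed reads, TPT1 with 709 and EIF3H with 370. Of cytosolic ribosomal proteins, 12 had a cluster: RPL17 had 42 reads in eIF3d and 794 in eIF3g, RPL23A had 501 in eIF3g and RPL24 had 188 summed reads, all in introns. RPS15A had between 70 and 136 reads per subunit in its 5′ UTR. Of splicing and hnRNP proteins, 12 had a cluster, all 12 with one in the 5′ UTR and 8 in all 4 subunits, with 490 summed reads in U2AF2, the large subunit of the splicing factor that binds polypyrimidine tracts, 293 in HNRNPA0, 185 in HNRNPAB and 175 in SRSF5. Of core and linker histones, 14 had a cluster, led by HIST1H2AD with 294 reads, H1FX with 280, HIST1H2BO with 172 and HIST1H1E with 130.

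Of cell cycle genes 8 had a cluster: CCNG1 had 401 summed reads, CDC25A, a phosphatase that activates cyclin-dependent kinases, 248, MCM7, a subunit of the replicative helicase, 204, in an intron, and CCND2, a cyclin, 139. Of anti-proliferative and tumour suppressor genes 4 had one: BTG1, NF2 with 68 reads, TXNIP with 66 and CDKN2A with 9. JUN was the 1 gene of 24 protein-coding members among immediate early and proto-oncogene transcription factors. BIRC5, an inhibitor of apoptosis, had 393 reads, most at its start codon, and PMAIP1, a pro-apoptotic gene, 28, the 2 genes of the apoptosis list.

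Of chaperones and heat shock genes, 8 had a cluster, with 149 summed reads in BAG3, 143 in CANX, 113 in TCP1 and 112 in STIP1. Of chromatin and transcription regulators, 10 had one, with 154 reads in BRD2, 122 in SMARCA5, 118 in CBX3 and 111 in HDAC2. The ubiquitin and proteasome list had 6, with 1618 reads in UBE2D2, 130 in PSMD14, 101 in UBB and 57 in UBE2V1. Smaller counts were 4 for Ras, MAPK and PI3K signalling (among them YWHAG with 77, SPRED1 with 40 and NRAS with 39 reads), 3 for the cytoskeleton (PFN1 86, TUBA1B 82 and CFL1 42) and 2 for core metabolism (SCD 414 and ENO1 137). Developmental transcription factors had 3 (among them HOXB6 with 14 and HOXA13 with 10 reads), and Wnt, Notch, Hedgehog and TGF-beta signalling had 1, ID4 with 23, in eIF3a alone. Of small structured and abundant noncoding RNAs, 11 had a cluster, led by MT-RNR2, RPPH1, the RNA of ribonuclease P, with 1055 reads, RNA5-8SP2 with 915 and MT-TP, a mitochondrial transfer RNA, with 558. The RNA5-8SP2 cluster with most reads had 780 conversions in 395 reads in eIF3b, 262 in 132 in eIF3a and 38 in 26 in eIF3g. The eIF3a and eIF3b values are near the level of the intronic clusters described below, and the source of these reads was not traced. No gene from the 20 markers of other cell types or the 10 genes associated with the 293T line had a cluster. By list size only 0.44 and 0.22 genes would be expected, so this absence says nothing about which cells were used.

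After adjustment 0 of 68 Fisher's exact tests of a list in a subunit against the other genes of the table passed, although only 32 of them had enough genes to be able to pass alone, and 2 were under an unadjusted 0.05, splicing and hnRNP proteins in eIF3b (11 of 12 genes, p = 0.0149) and in eIF3d (12 of 12, p = 0.0424). Against all protein-coding genes, 9 of 18 lists passed the threshold, each with more genes with a cluster than its size gives. Histones had 14 of 89 (odds ratio 8.48, adjusted p = 1.03e-07), splicing and hnRNP proteins 12 of 63 (10.7, adjusted p = 1.03e-07), translation factors 13 of 88 (7.86, adjusted p = 4.11e-07), ribosomal proteins 12 of 89 (7.05, adjusted p = 2.73e-06) and cell cycle genes 8 of 48 (8.98, adjusted p = 3.38e-05). The others were chromatin regulators (odds ratio 5.63), chaperones (4.42), anti-proliferative genes (9.37) and, at an adjusted p of 0.049 by Fisher's exact test, Ras, MAPK and PI3K signalling (3.87). The anti-proliferative list holds BTG1, which was known beforehand as an eIF3 target, so its result is not blind to that gene. With only 5′ UTR clusters, histones (4 of 89, adjusted p = 0.105 by Fisher's exact test) and Ras, MAPK and PI3K signalling (adjusted p = 0.0967) no longer passed and the cytoskeleton list did (adjusted p = 0.0341), and with clusters at or above the median reads Ras, MAPK and PI3K signalling had an adjusted p of 0.064. Among the translation factors, EIF3A, EIF3B, EIF3H, EIF3K and EIF3M are mRNAs of eIF3 subunits. Their clusters had a median of 0.0647 conversions per read in eIF3a, eIF3b and eIF3g, so RNA carried along without crosslinking is not excluded there. Expression was not measured, so strongly expressed genes are not separated from preferentially bound ones.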

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

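Scaling by reads in clusters, removal of loci with 1.9 or more conversions per read, the joint start codon class, direct overlap of a pair's clusters, leaving out EIF3A and the conversion summaries were chosen after seeing the data. No paired analysis was possible because the table carries no replicate column, and for the same reason no replicate could be left out and no counts per library could be tested; base composition was not run. Of 110 alternatives, 73 left a result in place, among them every one with a pseudocount of 0.1, with overlap by position or with gene and region pairs. Limiting the lists to clusters at or above their subunit's median reads left 188, 152, 204 and 213 clusters in eIF3a, eIF3b, eIF3d and eIF3g, by construction, and 94, 121, 109, 87, 94 and 119 genes shared by the pairs a-b, a-d, a-g, b-d, b-g and d-g, with 68 in all 4. It also moved the 5′ UTR share of eIF3g to 60.1%, the log2 difference of eIF3d from eIF3a to 0.086, no longer past the threshold, that of eIF3g from eIF3b to -0.10, and eIF3d conversions per read to 0.117. The log2 difference of eIF3g from eIF3a went from 0.00 to -0.26 (adjusted p = 0.0621 by permutation). It was counted as left in place because neither value passed the threshold. Without the other classes, 5′ UTR shares were 83.6%, 83.1%, 86.3% and 87.5%, from a smaller denominator, and the eIF3g share was 72.7% without loci at 1.9 or more conversions per read. With sites of a single subunit of a pair, 1 region test passed, and none without EIF3A. Ranks, which remove a shift common to all loci by construction, gave medians of -0.0066 (b from a), 0.0017 (d from a), 0.0033 (d from b) and -0.019 (g from b). Scaling by reads in clusters gave -0.61 (b from a), -0.52 (d from a), -2.04 (g from a), 0.034 (d from b), -1.48 (g from b) and -1.40 (g from d), all past the threshold except d from b. The few strong noncoding clusters of eIF3g enter that scaling, and so do the EIF3A clusters, with 5464 reads in eIF3b and 6132 in eIF3d against 382 in eIF3a. With all protein-coding genes as background, 34 of 72 tests of a list in a subunit passed. Histones and Ras, MAPK and PI3K signalling lost their call against all protein-coding genes with 5′ UTR clusters alone, and the signalling list also with the stricter clusters. Conversions per read as a ratio of sums were 0.917, 0.847, 0.0865 and 0.281, and at loci of all 4 subunits 0.135 in eIF3d and 1.06 in eIF3g. For changes not set by construction the cause was not tested. Low clusters, at 8 reads or a little more, limit the lists, since a gene absent from 1 list can lie just under the caller's threshold.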

Other observations

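All tests in this part were chosen after the data were seen, and genes outside the naming rule were named after their values were seen. Histone mRNAs differed from other mRNAs in where their clusters lay. Of 14 histone genes, 5 had a cluster called at the start codon (35.7%, Wilson interval 16.3 to 61.2), namely HIST1H1C, HIST1H1E, HIST1H2AD, HIST1H2BO and HIST1H3J, against 18 of 430 other protein-coding genes (4.19%, 2.66 to 6.52; Fisher's exact test, p = 0.00035). Another 4, H1FX, H2AFX, H3F3B and HIST1H2BN, had one in the 5′ UTR (28.6%), against 75.3% of the others. The difference was not particular to the start codon. Coding exon clusters were found in 5 of 14 histone genes (35.7%, 16.3 to 61.2) and in 44 of 430 others (10.2%, 7.71 to 13.5). The length of each 5′ UTR was not taken into account. Several genes carried more than 1 locus in the 5′ UTR: 36 of 331 had 2 or more, and AMOT and MTPN had 4 each.

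Clusters in genes that host small nucleolar RNAs took much of the eIF3g reads. Intronic and lincRNA clusters in 10 genes with an annotated snoRNA inside them, GAS5, GNL3, RBMX, RCC1, RPL17, RPL23A, SNHG1, SNHG15, SNX29 and SRCAP, held 31077 reads, 49.8% of the eIF3g total, against 4.82% in eIF3d, 0.813% in eIF3b and 0.469% in eIF3a. In eIF3g 9 further genes, among them RP11-329L6.1 with 7707 reads, matched no gene of the reference table. Their intronic and lincRNA clusters held 9163 reads, 14.7% of the eIF3g total, outside the share of the hosts. Whether a cluster lay on the snoRNA itself was not examined. The host clusters had a median of 0.0458 conversions per read in eIF3g, against 1.82 in the 33 eIF3g clusters of matched intronic and lincRNA genes without an annotated snoRNA, and in eIF3d 0.0411 against 0.124. The 1.82 is raised by intronic clusters at about 2 conversions per read, described below. Of 37 intronic eIF3g clusters, 15 reached 1.9, and the median over all eIF3g clusters was 1.02. In eIF3a and eIF3b the medians of the host clusters were 1.17 (3 clusters) and 1.09 (5 clusters), against 1.19 and 1.52, but most of these lay in hosts with few eIF3g reads: at the strongest eIF3g loci of GAS5 and SNHG1, eIF3b had 4 conversions in 16 reads and 2 in 13, and eIF3a had no cluster. Loci in coding exons were listed for all 4 subunits in 16.7% of 60 cases (Wilson interval 9.31 to 28), and those in 5′ UTRs in 31.9% of 376 (27.4 to 36.8).

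The low number of conversions in eIF3d, weighed first, was not a matter of other clusters in that list, since at loci of all 4 subunits the eIF3d median was 0.135 and the lowest other 1.02. A lower rate per read would keep conversions in proportion to reads. In 5′ UTR clusters the slope of log2 conversions on log2 reads was 0.38 in eIF3d (95% bootstrap interval 0.309 to 0.448). It was 0.851 to 0.999 in the other subunits, with a lowest bound of 0.729. Yet no cluster had fewer than 1 conversion, and such a floor can flatten the slope at a low rate. The 124 eIF3d clusters with 15 or fewer reads had a median of 4 conversions, above that floor, but the caller's thresholds are unknown. A constant low rate was not simulated, so the slope by itself does not exclude a lower rate. A candidate explanation is that the eIF3d entries count converted positions and not events: at 9 of 11 loci with 1.9 or more conversions per read in every other subunit that lists them, eIF3d had exactly 2 conversions, in 8 to 220 reads, and 3 and 6 at the others; at 2 of the 9 the eIF3d median rate would also give 2 or fewer, and at 7 it would give 3.64 to 40. The eIF3d entries exceeded the cluster's width in 2 clusters where the median rate would give 16. That rate is too high for strong clusters, since those with 100 or more eIF3d reads had a median of 0.0377 per read. The 40 and the 16 therefore overstate what a rate that falls with reads would give. The count of loci replaced a comparison of widths between subunits that could not tell the explanations apart, and its bounds were set with the values known. For a pair of EIF3A clusters the tables argue against a count of positions, with 39 conversions in 24 nt and 32 in 20 nt, and a biological difference of eIF3d at single loci stays open and untested.

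Clusters in mRNAs of eIF3 subunits carried few conversions in eIF3a, eIF3b and eIF3g, with a median of 0.0647 per read over 24 clusters in 5 genes, EIF3A, EIF3B, EIF3H, EIF3K and EIF3M, against 1.05 over 961 other mRNA clusters, though 19 of these, in 14 genes that include BTG1, TPT1, GNL3 and MCM7, were as low, with a median of 0.108. A read number of 100 or more does not by itself account for it. The 41 genes of other mRNA clusters with 100 or more reads had a median of 1.07, each gene counted 1 time (95% bootstrap interval 1.017 to 1.117). For the strongest EIF3A clusters in eIF3b, with 1411 to 1963 reads, that comparison cannot decide. At such depth JUN and BTG1 in eIF3g, with 1735 and 3109 reads, had only 0.0818 and 0.0946 conversions per read. RNA or DNA carried along without crosslinking may account for the low conversions, and the noncoding clusters of the same lists had a median of 0.364, but no value here tells RNA from DNA. Capture of these mRNAs through nascent eIF3 chains is a biological hypothesis that also stays open: EIF3A had more reads than EIF3B in 3 of 4 subunits, which does not decide it, since nascent eIF3a could itself be bound by eIF3b.

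Many intronic clusters carried about 2 conversions in nearly every read, and none in any list went above 2. In eIF3a, eIF3b and eIF3g, 18 of 43 intronic loci, each counted 1 time over the 3 lists, had a cluster that reached 1.9 (41.9%, Wilson interval 28.4 to 56.7), against 2 of 350 in 5′ UTRs (Fisher's exact test, p = 1.93e-17), with FGFR2 at 1049 conversions in 525 reads in eIF3b. Short width alone does not account for it. None of the 84 5′ UTR loci with clusters of 21 nt or less reached 1.9 (0%, upper Wilson bound 4.37), against 15 of 24 in introns. A contribution of width stays open, since 62.5% of intronic loci with such short clusters reached 1.9, against 41.9% of all intronic loci. The short clusters were also not matched, with a median width of 19 nt in introns and 21 nt in 5′ UTRs. A candidate explanation is reads of another RNA or locus that were placed with 2 fixed mismatches. Their source was not traced, because the genome sequence is not used here, and no biological explanation was tested.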
